A study of Mus musculus with 10 samples.

How the data were processed

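RNA from sorted mouse CD4 CD8 double-positive (DP) thymocytes was hybridised to 10 Affymetrix expression arrays, one array per mouse. Per the labels, all mice carried Cd4-cre, were 8 weeks old and gave DP cells of over 98% purity, with about 1000000 cells sorted and 6 µg of RNA used. The groups were Cd4-cre control (WT, n = 3), loss of E2A (E2AKO, n = 2), loss of HEB (HEBKO, n = 2) and loss of both (DKO, n = 3).

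The deposited values are intensity values on a linear scale. The authors processed them by RMA (background correction, quantile normalisation between arrays at the probe level and summarisation per probe set), and they state no RMA version. They were turned to log2 with no added constant. For arrays, the number of arrays limits the precision. Of 34760 probe sets, 21640 carried 1 gene symbol, 1321 carried several and 11799 carried none. The latter 2 kinds were left out of the gene counts. Each of the 19937 named genes was represented by its probe set with the highest mean over the 10 arrays. A gene was tested if that probe set reached the 40th percentile of the array in at least 2 arrays, which kept 13138 genes and left out 6799. No genome sequence was at hand, so gene positions are not given and a table of gene models served only for symbols and for the order of neighbouring genes.

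A linear model with 1 mean per genotype was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the spread (residual degrees of freedom 6, prior degrees of freedom 5.68, median gene SD 0.14 log2 units). The 7 contrasts tested were each knockout against WT, the 3 differences between knockouts, and the interaction DKO - E2AKO - HEBKO + WT, which measures the departure from additivity on the log2 scale. Each p is two-sided and was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. On simulated unchanged data with 200 changed genes the same steps were tested for recovery at known folds. Errors beside fold changes are standard errors (SE) from the fit unless given as SD. The fits share the spread of all 4 groups because 2 of them hold 2 arrays each. A change called a lower bound is still an estimate with its own error. The term marks genes near background, where the size of a change can be understated. The 3 comparisons against WT share the same WT arrays, so their overlap was set beside groups simulated as unchanged against shared WT arrays, in 100 draws.

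Before the data were examined, 25 gene lists were fixed for this tissue, of stage, signalling, lineage, cell cycle, metabolic and stress genes, and of markers of other cell types. Of their 400 genes, 362 were on the array and 312 were tested. The 22 lists with at least 5 tested members were tested with camera in limma, at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over lists within a comparison. Camera was repeated with a correlation estimated per list, and fry was run beside it. Members are counted as called over all genes, and also adjusted over the list alone. The named genes were fixed by rule, also in advance: Tcf3 and Tcf12, the 12 largest rises and the 12 largest falls against WT among called genes whose groups did not overlap in any array (6 and 6 for other contrasts), up to 4 members of each list with the largest change, and 12 further genes, 11 of them tested. Symbols of clones and predicted genes were passed over. Mcl1, Bid, Casp8, Gata3, Socs3, Tox, Gfi1 and Nfatc3 in DKO, Cd5 in HEBKO, and the genes named only under other observations lie outside this rule and were chosen after their values were seen.

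Alternatives tried for the gene counts were no intensity filter, a filter at the 60th percentile, renewed quantile normalisation, a shift of the arrays to 1 median, the mean of a gene's probe sets, eBayes with trend and robust (with statmod 1.5.0), array weights, only the groups compared, the replicate number as a block, a minimum of 2-fold, and leaving out each array in turn. Named genes were not run with only the groups compared or with the 2-fold minimum, and a gene removed by a filter was skipped there. Lists were run with the other list tests, no filter, renewed quantile normalisation, the block and arrays left out. Overlaps were run with fewer alternatives. A term for sex, and a split of the WT arrays between HEBKO and DKO, were added after the data were seen. Sex was read from Xist and 3 genes of the Y chromosome.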

Results

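Transcripts of DP thymocytes, the stage at which the T cell receptor alpha locus rearranges and cells await selection, were measured in 10 mice of 4 genotypes. The design asked how these cells differ when they lack the basic helix-loop-helix transcription factors E2A (gene Tcf3), HEB (gene Tcf12) or both. WT had n = 3, E2AKO n = 2, HEBKO n = 2 and DKO n = 3. Median intensity over all probe sets ran from 92.6 to 98.6 across the arrays. The correlation of log2 values across genes was 0.980 to 0.989 between WT arrays and 0.949 to 0.973 between WT and DKO arrays (genes are not independent replicates). Xist and the Y-linked genes showed 1 female in WT, 1 in E2AKO, 1 in HEBKO and 2 in DKO, so each genotype held both sexes.

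The targeted transcripts were lower in every array of the matching knockouts. Tcf3 was 9.65, 9.85 and 9.63 (log2 intensity) in WT 1 to 3, 9.23 and 9.12 in E2AKO 1 and 2, 10.02 and 10.06 in HEBKO 1 and 2, and 9.29, 8.93 and 8.94 in DKO 1 to 3. Mean Tcf3 intensity was 68.7% of WT in E2AKO, 126% in HEBKO and 63.7% in DKO. Tcf12 was 11.91, 11.74 and 11.86 in WT 1 to 3, 11.93 ± 0.09 (mean and SD, n = 2) in E2AKO, 11.15 and 11.48 in HEBKO, and 10.68, 10.73 and 10.71 in DKO. Mean Tcf12 intensity was 70.0% of WT in HEBKO and 45.7% in DKO. Tcf3 fell by 0.66 ± 0.11 (log2, SE) in DKO (limma adjusted p = 0.00256), and Tcf12 fell by 1.13 ± 0.10 (adjusted p = 3.07e-05). The single knockouts did not pass the test over all genes, with Tcf3 at -0.54 ± 0.13 in E2AKO (adjusted p = 0.998, 95% interval -0.82 to -0.26) and Tcf12 at -0.52 ± 0.12 in HEBKO (adjusted p = 0.0657), which passed when the arrays were quantile normalised again (-0.59), with trend and robust moderation (-0.52), with array weights (-0.53), without WT 2 (-0.57) or without HEBKO 2 (-0.69). Tcf12 was 0.61 ± 0.12 lower in DKO than in HEBKO (contrast -0.61, adjusted p = 0.0136). Each gene had 1 probe set read over the whole transcript, and the deleted exons are not given here, so the residual signal does not measure intact messenger RNA.

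**Figure D1:**
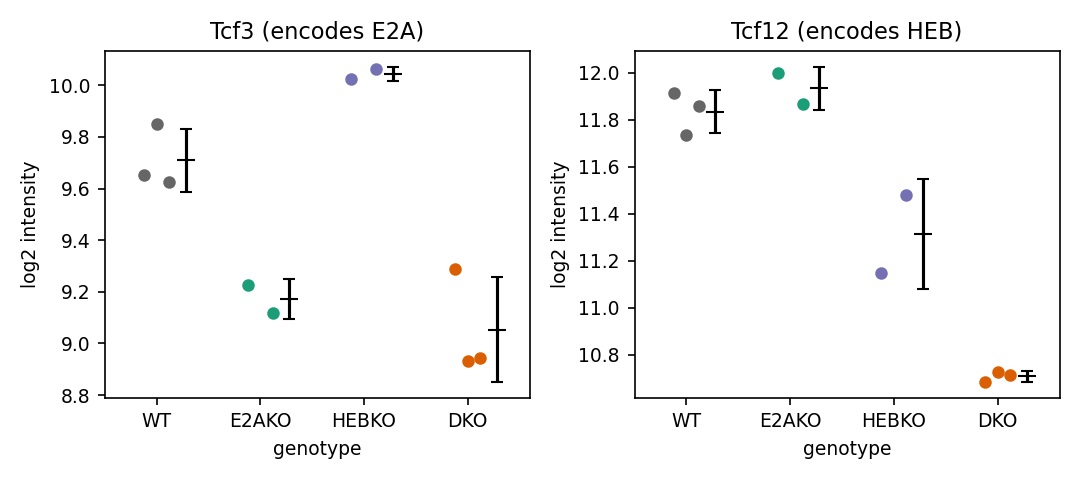
Log2 intensity (y axis) of Tcf3 and Tcf12 in each array (points) by genotype (x axis), with the group mean and SD beside the points. Tcf3 lay between 8.93 and 9.29 in DKO and between 9.63 and 9.85 in WT, and Tcf12 lay between 10.68 and 10.73 in DKO and between 11.74 and 11.91 in WT.

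Loss of E2A alone left no gene past the test against WT (0 of 13138 genes in limma, n = 2 against n = 3, smallest adjusted p = 0.998). At an unadjusted p under 0.05 there were 418 genes, where chance gives 656.9. Among the genes named for this comparison, leaving out the sex-linked list, the largest differences were Cldn4, a tight junction protein, at -0.71 ± 0.14, Il7r, the receptor of interleukin 7, at 0.57 ± 0.34, Tcf3 at -0.54 ± 0.13, Il2ra at 0.50 ± 0.22 and Bst2 at -0.46 ± 0.17, none past the test. Il7r lay below the 40th percentile of the array in all 3 WT arrays and 1 E2AKO array, so its value and rank are not measured. Rag1, Rag2, Cd4 and Cd8a were not called either. Over the list alone, Tcf3 was the 1 E and Id protein and Cldn4 the 1 thymic epithelial marker below the threshold. No list of the 22 tested was called (0 lists by camera, 0 by fry and 0 with an estimated correlation), and the lowest camera adjusted p was 0.0581 for thymic epithelial markers, with a median of -0.15 over 8 genes. Some alternatives given below did call lists. On simulated data with 200 changed genes the E2AKO comparison recovered 94.6% of 2-fold changes and 61.2% of 1.5-fold changes. With fewer changed genes the threshold after adjustment is stricter, so these shares do not apply to rare changes. Tcf3 itself, at an unadjusted p of 0.00124 in limma, did not pass.

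Loss of HEB alone changed 119 genes, 36 up and 83 down (n = 2 against n = 3), of which 5 and 16 reached 2-fold, a balance that turned in 2 alternatives given below. The largest falls were Myzap at -1.83 ± 0.17 (adjusted p = 0.0019), Smoc1, a secreted calcium-binding protein, at -1.66 ± 0.25, Ldlrad3 at -1.57 ± 0.22, Plxdc1 at -1.43 ± 0.18, Gramd3 at -1.42 ± 0.29, Car2, a carbonic anhydrase, at -1.41 ± 0.17, and Fmnl2, a formin that acts on actin, at -1.40 ± 0.17. Lrrc1 (-1.27), Gbp8 (-1.17), Scn4b (-1.16), Lrig1 (-1.16) and P2rx1, an ATP-gated channel (-1.15), also fell. The largest rises were Vim, an intermediate filament protein, at 1.13 ± 0.21, Atp8b4 at 1.10 ± 0.14, Gpr65, a proton-sensing receptor, at 1.09 ± 0.19, Cpm at 1.05 ± 0.17 and Ms4a6b at 1.00 ± 0.16. Nop10 (0.97), Cox7b (0.95), Slc37a4 (0.94), Ndufc2 (0.94), Snord14e (0.91), Pqlc3 (0.91) and Shmt2 (0.90) rose too. Below the 40th percentile of the array lay Car2 in both HEBKO arrays, Myzap in 1 of them, Atp8b4 in all 3 WT arrays and Cpm in 1, so these values are lower bounds on the size of the change. Outside these, Il21r, the interleukin 21 receptor, fell (-1.01 ± 0.12), Bcl2l1, which encodes the survival protein Bcl-xL, fell (-0.65 ± 0.12, adjusted p = 0.032) and Ikzf2 rose (0.65 ± 0.11). Cd4 at -0.67 ± 0.15 (adjusted p = 0.072), Rag1 at -0.43 ± 0.18, Rag2 at -0.51 ± 0.25, Il7r at 0.64 ± 0.34, Ptcra at -0.31 ± 0.15 and Id3 at -0.08 ± 0.26 did not pass, and Il7r, below that percentile in all 3 WT arrays and 1 HEBKO array, has no measured fold.

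For HEBKO, camera at its preset correlation called S-phase, mitosis, glycolysis and mature single-positive genes up and DP-stage genes and thymic epithelial markers down, and no call held with an estimated correlation (0 of 22 lists). None of 24 S-phase genes, such as the replication genes Prim1 (0.82 ± 0.20), Cdc6 (0.77 ± 0.24) and Mcm5 (0.68 ± 0.18), was called over all genes (0 called), and 17 were when adjusted over the list alone. Their median was 0.53 (camera adjusted p = 1.43e-10, and adjusted p = 0.547 with an estimated correlation). The median per array, from the WT mean, was 0.57 and 0.51 in HEBKO and -0.10, 0.26 and -0.10 in WT. The 23 mitosis genes, such as Bub1 at 0.72 and Cdk1 at 0.71, had a median of 0.39 with 0 called and 0 adjusted over the list alone (adjusted p = 1.35e-05, and adjusted p = 0.547 with an estimated correlation). Their median per array was 0.26 and 0.51 in HEBKO 1 and 2 and -0.12, 0.24 and -0.08 in WT, so HEBKO 1 lay close to WT 2. The 12 glycolysis genes, such as Tpi1 at 0.87, had a median of 0.27 with 0 called by either adjustment, over all genes or adjusted over the list alone (adjusted p = 0.000864, and adjusted p = 0.547 with an estimated correlation).

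Of 22 DP-stage genes in HEBKO, Plxnd1, a semaphorin receptor that guides DP cells in the thymus, fell (-1.07 ± 0.14) and 21 did not pass, while 5 fell and 1 rose adjusted over the list alone (camera down, adjusted p = 0.000331, and adjusted p = 0.547 with an estimated correlation). Of 19 mature single-positive genes, Ms4a6b rose and 18 did not pass, while 2 rose adjusted over the list alone (median 0.24, adjusted p = 0.0292, and adjusted p = 0.58 with an estimated correlation). Gimap3 at 1.22 ± 0.29 and Gimap4 at 1.02 ± 0.43 were among those 18, with Gimap3 a lower bound since it lay below the 40th percentile of the array in 2 of 3 WT arrays. Without HEBKO 1 the median of this list was -0.06. In the list of thymic epithelial markers Cldn4 was lower (-1.01 ± 0.14, called), with 7 of 8 not past the test and 3 lower adjusted over the list alone (median -0.30, camera adjusted p = 0.00692, and adjusted p = 0.375 with an estimated correlation). Fry called 1 of the 22 lists, the thymic epithelial markers, and camera called 6. Both HEBKO arrays differed in Il7r (6.90 and 5.64), Id3 (8.66 and 7.48), Cd5 (10.77 and 9.98) and Rag2 (9.93 and 10.80). The count of 119 fell to 2 without HEBKO 1, 13 without WT 3, 24 without WT 1, 55 without DKO 2 and 76 without DKO 1, reached 492 without WT 2 (357 up and 135 down) and 515 with array weights (306 up and 209 down), both with more rises than falls, and was 36 in a fit of the groups compared alone and 73 with arrays shifted to 1 median. Myzap and Il21r stayed past the test in every alternative run.

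Loss of both factors changed 1786 genes against WT (n = 3 against n = 3), 1075 up and 711 down, of which 144 and 132 reached 2-fold. The recombinase genes Rag1 and Rag2 fell 3.11-fold and 3.9-fold, the coreceptor gene Cd4 fell 3.67-fold, and the survival gene Bcl2l1 fell 3.05-fold. Genes of mature T cells rose, such as Gimap3 (16.3-fold), Ms4a4b (9.35-fold), Il7r (8.58-fold), the chemokine receptor gene Ccr7 (6.26-fold) and S1pr1, needed for exit from the thymus (6.1-fold). Il7r in all 3 WT arrays and Gimap3 in 2 of 3 lay below the 40th percentile of the array, so their folds are to be read as lower bounds.

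Kcnma1, a potassium channel gene, had the largest mean rise (5.27 ± 1.55, adjusted p = 0.043), at 12.99 and 12.19 in DKO 1 and 2 but 4.97 in DKO 3, against 4.69 to 4.84 in WT. Its call was lost without any of the arrays WT 1 to 3, E2AKO 1 and 2, HEBKO 1 and 2, or DKO 1 and 2. The next rises were Gimap3 at 4.02 ± 0.26 (adjusted p = 2.5e-06), Cd226, an activating receptor, at 3.79 ± 0.26, Il18r1, a chain of the interleukin 18 receptor, at 3.50 ± 0.11 (adjusted p = 1.5e-08), Ms4a4b at 3.22 ± 0.31, Il7r at 3.10 ± 0.31, Cpm at 2.90 ± 0.15 and Gria3, a glutamate receptor subunit, at 2.89 ± 0.20. Card6 (2.84), Atp8b4 (2.84), Tent5c (2.74) and Gpr65 (2.74) completed the 12. Il18r1, Gria3, Card6 and Atp8b4 lay below the 40th percentile of the array in all 3 WT arrays and Cpm in 1, so their rises are lower bounds. Kcnma1 did in all 3 WT arrays and in DKO 3, so its mean difference stands for no measured fold. The largest falls were Slc7a11, the cystine transporter, at -3.17 ± 0.30, Dhrs3, a retinal reductase, at -3.05 ± 0.29, F13a1, a coagulation factor chain, at -2.90 ± 0.12, Plxnd1 at -2.88 ± 0.13, Mir181a-1, a microRNA that tunes T cell receptor signalling, at -2.80 ± 0.31 and Iftap at -2.76 ± 0.31. Smoc1 (-2.67), Ldlrad3 (-2.52), Aqp11 (-2.50), Fmnl2 (-2.42), Cd5 (-2.34) and Mir181b-1 (-2.31) followed. Mir181a-1 and Mir181b-1 are neighbours in the order of tested genes, so their falls may not be separate. Whether the mature microRNAs fell was not tested. Mir181a-1 in 2 of 3 DKO arrays and Fmnl2 in 1 lay below that percentile, so their falls are lower bounds on size.

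The DP program was lower in DKO. Of 22 DP-stage genes 11 fell, 1 rose and 10 did not pass, with the same 11 and 1 counts adjusted over the list alone (camera adjusted p = 1.75e-08, and adjusted p = 0.192 with an estimated correlation). Plxnd1, Rag2 (-1.96 ± 0.22), Ets2 (-1.93 ± 0.16) and Arpp21 (-1.89 ± 0.18) fell most, Cd4 fell by 1.88 ± 0.14 and Cd8a by 0.45 ± 0.10. Sh2d1a, which encodes the signalling adaptor SAP, rose (0.77 ± 0.11). Of 14 genes of V(D)J recombination and end joining 6 fell and 2 rose, and 6 fell and 3 rose adjusted over the list alone (adjusted p = 0.0464, and adjusted p = 0.41 with an estimated correlation). Lig4, the end-joining ligase, fell (-1.65 ± 0.12) and Dntt, which adds bases at junctions, fell (-0.99 ± 0.14), keeping 50.2% of WT where Rag2 kept 25.6%. The call of that list was lost without WT 2, E2AKO 1, E2AKO 2 or DKO 1, with no filter and with renewed quantile normalisation. Ptcra at -0.24 ± 0.13 and Cd3e at -0.27 ± 0.10 did not pass.

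Genes that T cell receptor signals induce were also lower in DKO. Of 20 TCR-induced genes 11 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone (median -0.69, adjusted p = 1.06e-07, and adjusted p = 0.239 with an estimated correlation). Cd5, a negative regulator of receptor signalling, fell by 2.34 ± 0.19, the nuclear receptor gene Nr4a1 by 1.83 ± 0.24, Id3 by 1.63 ± 0.23 and the phosphatase gene Dusp6 by 1.38 ± 0.16, while Myc rose (1.25 ± 0.20). Of 7 E and Id protein genes 4 fell (Tcf3, Tcf12, Id2 and Id3), also 4 adjusted over the list alone (adjusted p = 0.00299, and adjusted p = 0.17 with an estimated correlation). This list holds both deleted genes. Id2 at -0.55 ± 0.14 lay below the 40th percentile of the array in all 3 DKO arrays, so its fall is a lower bound on size, and it lost its call without WT 2, WT 3, DKO 2 or DKO 3. Of 22 genes of the receptor complex and its proximal signalling 5 rose and 4 fell, 6 and 5 adjusted over the list alone (adjusted p = 0.654). Cd6 (-1.74 ± 0.10) and Cd247 (-0.69 ± 0.10) fell and Ptpn22 rose (0.69 ± 0.12).

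Apoptosis regulators moved down as a list, although its members act in both ways. Of 19 genes 6 fell and 1 rose, 7 and 2 adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.17 with an estimated correlation). The pro-survival genes Bcl2l1 (-1.61 ± 0.11), Bcl2 (-0.61 ± 0.18) and Mcl1 (-0.33) fell, as did the pro-death genes Bmf (-1.79 ± 0.22), Bcl2l11 (-0.62 ± 0.13) and Bid (-0.42), and the initiator caspase gene Casp8 rose (0.57). Bcl2 lost its call without WT 1, WT 2, WT 3, E2AKO 1, E2AKO 2, DKO 1 or DKO 2, with no filter and with arrays shifted to 1 median. Mcl1 lost it without any 1 array except WT 3, Bid without WT 2, WT 3, DKO 2 or DKO 3, and Casp8 without WT 1, WT 3 or DKO 3.

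The mature single-positive list rose most. All 19 tested members were called, 17 up and 2 down, with the same 17 and 2 adjusted over the list alone (median 2.14, camera adjusted p = 9.6e-16, and adjusted p = 0.17 with an estimated correlation). Besides Gimap3, Ms4a4b and Il7r, Ccr7 rose by 2.65 ± 0.19, S1pr1 by 2.61 ± 0.29, Runx3, a factor of the CD8 lineage, by 2.14 ± 0.22 and Foxo1 by 1.47 ± 0.19. Gata3, a factor of the CD4 lineage (-0.56, call lost without WT 3 or DKO 2), and Socs3 (-0.68) fell. In the list of thymic epithelial markers Cldn4 (-1.26 ± 0.12) and Epcam (-0.54 ± 0.11) fell and 6 of 8 did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.193 with an estimated correlation). The call of that list was lost without WT 1 and with renewed quantile normalisation. Whether the signal of these 2 genes came from epithelial or DP cells was not tested. Epcam lay below the 40th percentile of the array in all 3 DKO arrays and 1 WT array, so its fold is not measured. Of 19 T-lineage transcription factor genes 4 rose and 8 fell, 4 and 9 adjusted over the list alone, with Runx3, Rora (2.07 ± 0.26, with 1 WT array below that percentile), Foxo1 and Tox (0.64, call lost without any 1 WT, E2AKO or DKO array) up and Myb (-1.40 ± 0.11), Gfi1 (-0.94) and Nfatc3 (-0.85) among those down. The list median was -0.21, its mean 0.01 and the direction of the test down (adjusted p = 0.0277, and adjusted p = 0.378 with an estimated correlation), a call lost without DKO 2.

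Of 11 NKT and cytotoxic genes in DKO, 5 rose and 1 fell, also 5 and 1 adjusted over the list alone (adjusted p = 0.0279, and adjusted p = 0.215 with an estimated correlation). Nkg7 (1.89 ± 0.25) and the cathepsin gene Ctsw (1.62 ± 0.20) of cytotoxic granules rose, Zbtb16, the NKT factor PLZF, rose (0.59 ± 0.14, call lost without WT 3 or DKO 3) and Slamf1 fell (-0.85 ± 0.18). Nkg7 lay below the 40th percentile of the array in 2 of 3 WT arrays, so its rise is a lower bound. The list was not called without WT 2 or DKO 1, or with no filter. Of 20 cytokine receptor and signalling genes 7 rose and 7 fell, 8 and 7 adjusted over the list alone (adjusted p = 0.436), with Il18r1, Il7r and Il17rb (1.56 ± 0.22) up and Il4ra (-1.25 ± 0.13) down. Of 20 migration and adhesion genes 5 rose and 4 fell, 6 and 5 adjusted over the list alone (adjusted p = 0.611), among them Ccr4 (1.59 ± 0.28) up. Of 17 early thymocyte and Notch target genes 4 rose and 2 fell, also 4 and 2 adjusted over the list alone (adjusted p = 0.707, median -0.08, mean 0.34), with Il2ra (2.17 ± 0.20) and Dtx1 (1.57 ± 0.14) up. Il2ra was also the 1 of 8 regulatory T cell genes that rose (1 adjusted over the list alone, adjusted p = 0.707), and Zbtb16 the 1 of 7 gamma-delta lineage genes (1 adjusted over the list alone, adjusted p = 0.819).

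Few proliferation genes were called in DKO. Of 24 S-phase genes Gins2 fell (-0.51 ± 0.13, call lost without WT 1, WT 2, DKO 2 or DKO 3) and 23 did not pass, 1 lower adjusted over the list alone (median -0.03, adjusted p = 0.671). None of 23 mitosis genes was called (0 called, 0 adjusted over the list alone), with Ccna2 at -0.45 ± 0.20 and Mki67 at -0.42 ± 0.16, although the list was called down (median -0.24, adjusted p = 0.0187, and adjusted p = 0.747 with an estimated correlation), a call lost without WT 2 or DKO 3. Of 12 glycolysis genes Slc2a3, a glucose transporter (0.58 ± 0.10), and Aldoa (0.57 ± 0.12) rose, 6 adjusted over the list alone (median 0.28, adjusted p = 0.00376, and adjusted p = 0.41 with an estimated correlation). Of 12 interferon-stimulated genes 4 rose, also 4 adjusted over the list alone, among them Ifit1 (1.18 ± 0.35), Irf9 (0.63 ± 0.19) and Irf1 (0.57 ± 0.10) (adjusted p = 0.0193, and adjusted p = 0.602 with an estimated correlation). The list median per array was 0.87 in DKO 1, 0.06 in DKO 2 and 0.16 in DKO 3, and the call was lost without DKO 1. Ifit1, below the 40th percentile of the array in all 3 WT arrays and so a lower bound, lost its call without any 1 WT, E2AKO or HEBKO array, and Irf9 without WT 1, WT 3, E2AKO 1, E2AKO 2, DKO 1 or DKO 3. Of 16 stress and immediate-early genes 3 fell, also 3 adjusted over the list alone, with Btg2 (-0.91 ± 0.12) and Jund (-0.70 ± 0.13) (adjusted p = 0.285).

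Among markers of other cells in DKO, Cd79b was the 1 of 7 B cell genes that fell (-0.59 ± 0.13, call lost without DKO 3, 1 adjusted over the list alone, list adjusted p = 0.436). Of 6 myeloid genes Ctss, a protease of antigen-presenting cells, rose (1.55 ± 0.19) and Itgam fell (-0.67 ± 0.15), 1 and 1 adjusted over the list alone (adjusted p = 0.783). Ctss in 2 of 3 WT arrays and Itgam in 1 DKO array lay below the 40th percentile of the array, so both are lower bounds on size. None of 2 erythroid and 4 stromal genes was called (0 and 0, 0 adjusted over the list alone), Alas2 being at -0.16 ± 0.11 (1 DKO array below that percentile) and Col1a2 at -0.07 ± 0.10. None of 4 sex-linked genes was called (0 called, 0 adjusted over the list alone). Fry called 12 of the 22 lists in DKO, not the same lists as camera. It did not call mitosis genes (fry adjusted p = 0.492) or interferon-stimulated genes (fry adjusted p = 0.178). It did call cytokine receptor and signalling genes (fry adjusted p = 0.00488) and stress and immediate-early genes (fry adjusted p = 0.0321), which camera did not. The count of 1786 was 991 without WT 3, 1037 without DKO 3, 1127 without DKO 2 and 3655 with array weights.

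**Figure D2:**
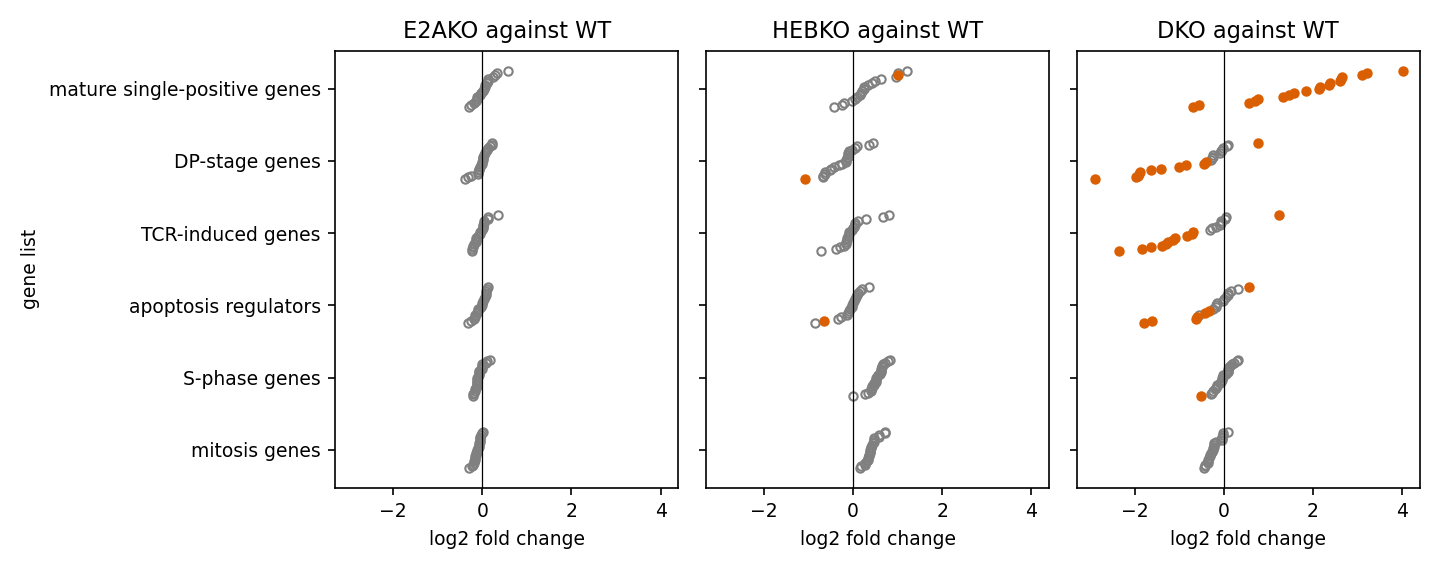
Log2 fold change against WT (x axis) of the tested members of 6 gene lists (y axis) in E2AKO, HEBKO and DKO, each point 1 gene, filled where the gene passed the test over all genes. In DKO 17 of 19 mature single-positive genes rose, and 11 of 22 DP-stage and 11 of 20 TCR-induced genes fell, while in HEBKO the 24 S-phase genes had a median of 0.53.

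The changes of HEBKO and DKO overlapped. Of the 119 genes called in HEBKO, 100 were called in the same direction in DKO (26 up, such as Atp8b4 and Gpr65, and 74 down, such as Smoc1 and Fmnl2), where independent lists would share 2.95 and 4.49. The other 19 were not called in DKO. The correlation of the fold changes across genes was 0.614, against 0.444 (0.374 to 0.532) for simulated unchanged groups that share the WT arrays, and the covariance was 0.0525 against 0.0088. Simulated groups shared at most 1 called gene, which follows from their being unchanged and so is no yardstick for the 100. With the WT arrays split so that HEBKO and DKO were compared with different ones (1 array for one and 2 for the other, 6 ways, chosen after the data were seen), the covariance was 0.0288 to 0.0514. The genes called in both were then 0 to 98, with 0 to 496 called in HEBKO. E2AKO and HEBKO shared 0 called genes in limma, since E2AKO had 0 called and 418 at an unadjusted p under 0.05. Their correlation was 0.254 against a simulated 0.402. The covariance was 0.0086 against 0.00885. For E2AKO and DKO the correlation was 0.318 against 0.444, while the covariance was 0.0159 against 0.00878, a difference of 0.00714.

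Between the single knockouts, 5 genes differed (n = 2 against n = 2). Atp8b4 was higher in HEBKO than in E2AKO (1.09 ± 0.15), and Myzap (-1.94 ± 0.18), Fmnl2 (-1.62 ± 0.19), Lrig1 (-1.24 ± 0.17) and Gbp4, an interferon-inducible GTPase (-0.74 ± 0.10), were lower. Atp8b4 in both E2AKO arrays and Myzap in 1 HEBKO array lay below the 40th percentile of the array, so both differences are lower bounds on size. Over lists, 4 were called, with S-phase, mitosis and glycolysis genes higher in HEBKO and DP-stage genes lower. The S-phase median was 0.61, with 0 of 24 called and 21 adjusted over the list alone (adjusted p = 3.16e-11, and adjusted p = 0.55 with an estimated correlation). For mitosis genes the median was 0.52 (0 called, 0 adjusted over the list alone), for glycolysis 0.27 (0 called, 3 adjusted over the list alone) and for DP-stage genes -0.22 (0 called, 2 adjusted over the list alone), each with adjusted p = 0.55 with an estimated correlation. Both E2AKO arrays lay far apart, with medians from the WT mean of 0.18 and -0.37 for S-phase and 0.18 and -0.44 for mitosis genes. Without E2AKO 2 the S-phase median was 0.30, the mitosis median 0.17 and the glycolysis median 0.17, the latter 2 no longer called, and without E2AKO 1 the first 2 were 0.89 and 0.84. Without HEBKO 1 the DP-stage median was -0.10. Fry called 0 lists here. The count of 5 was 0 without E2AKO 2, 1 without E2AKO 1, 1 without HEBKO 1, 2 without WT 3, 2 without DKO 2, 9 without WT 1, 10 without WT 2 and 55 without HEBKO 2. It was 22 with trend and robust moderation and 3 in a fit of the groups compared or with arrays shifted to 1 median.

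DKO cells differed from E2AKO cells in 1191 genes (n = 3 against n = 2), 670 higher and 521 lower. Gimap3 (3.79 ± 0.29), Il18r1 (3.70 ± 0.12), Cd226 (3.45 ± 0.29), Ms4a4b (3.41 ± 0.35), Gria3 (2.85 ± 0.23) and Atp8b4 (2.83 ± 0.14) were the largest of the genes higher in DKO. Slc7a11 (-3.11 ± 0.33), Iftap (-2.98 ± 0.34), Mir181a-1 (-2.95 ± 0.35), F13a1 (-2.93 ± 0.14), Fmnl2 (-2.64 ± 0.17) and Dhrs3 (-2.61 ± 0.32) were the largest of the lower ones. These 12 genes stayed past the test in all alternatives run for named genes. Below the 40th percentile of the array lay Il18r1, Gria3 and Atp8b4 in both E2AKO arrays, Gimap3 in 1, Mir181a-1 in 2 DKO arrays and Fmnl2 in 1, so their differences are lower bounds on size and their order is not fixed. Of 22 lists 9 were called, 3 up and 6 down, with 17 of 19 mature single-positive genes higher (17 adjusted over the list alone, adjusted p = 0.165 with an estimated correlation) and 10 of 22 DP-stage genes lower (12 adjusted over the list alone, adjusted p = 0.165 with an estimated correlation). None of the 9 kept its call with an estimated correlation (0), and fry called 10, not all of them the same lists. Interferon-stimulated genes were called by camera and not by fry (fry adjusted p = 0.154). The count of 1191 was 588 without E2AKO 1, 619 without E2AKO 2 and 773 without DKO 3.

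DKO cells differed from HEBKO cells in 477 genes (n = 3 against n = 2), 282 higher and 195 lower. Il18r1 (an estimated 9.17-fold), Cd226 (3.13 ± 0.29), Gimap3 (2.80 ± 0.29), Card6 (2.75 ± 0.18), Ms4a4b (2.73 ± 0.35) and Gria3 (2.72 ± 0.23) were higher in DKO. Cd5 (-2.19 ± 0.22), F13a1 (-2.13 ± 0.14), Slc7a11 (-2.05 ± 0.33), Iftap (-1.95 ± 0.34), Dhrs3 (-1.83 ± 0.32) and Plxnd1 (-1.81 ± 0.14) were lower. Il18r1 and Gria3 lay below the 40th percentile of the array in both HEBKO arrays and Card6 in 1, so their differences are lower bounds. S-phase genes had a median of -0.56 (1 lower over all genes, 18 adjusted over the list alone) and mitosis genes of -0.64 (0 called over all genes, 22 adjusted over the list alone), each called down with adjusted p = 7.38e-13, and with adjusted p = 0.25 with an estimated correlation. Of 19 mature single-positive genes 14 were higher and 1 lower (17 and 1 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), and of 20 TCR-induced genes 8 were lower (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.177 with an estimated correlation). In all, 11 of 22 lists were called, 0 with an estimated correlation and 8 by fry. Slc7a11, Iftap and Dhrs3 lost their call without HEBKO 2, where the count was 193, and it was 230 without DKO 3.

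The interaction term asked whether loss of both factors changed a gene by more or less than the sum of the single losses on the log2 scale. It passed the test in 83 genes, 67 positive and 16 negative (n = 3, 2, 2 and 3), and 1145 had an unadjusted p under 0.05 in limma, where chance gives 656.9. All 83 lay beyond the sum in the direction of the DKO change. Of them 81 were called in DKO, 12 in HEBKO and 0 in E2AKO by limma. In the positive genes the median change was -0.03 in E2AKO, 0.08 in HEBKO and 1.70 in DKO, and in the negative genes -0.08, -0.42 and -1.67. The genes were chosen by this term on the same arrays. Large DKO changes beside small single changes, and the shared direction of all 83, thus follow in part from that choice. The largest positive terms were Il18r1 (3.40 ± 0.18, adjusted p = 4e-06), Ms4a4b (2.92 ± 0.49), Cd226 (2.80 ± 0.41), S1pr1 (2.74 ± 0.46), Gria3 (2.68 ± 0.32) and Card6 (2.64 ± 0.25). Of the 67 positive genes, 7 lay below the 40th percentile of the array in all 7 arrays of WT, E2AKO and HEBKO, among them Il18r1 and Gria3. Card6 did in all 3 WT arrays, both E2AKO arrays and 1 HEBKO array, and S1pr1 in 1 E2AKO and 1 HEBKO array. The single losses were thus not fully measured for these 4 genes, and neither their terms nor their order is fixed. The largest negative terms were F13a1 (-2.16 ± 0.19), Cd5 (-1.95 ± 0.31), Plxnd1 (-1.49 ± 0.20), Cd6 (-1.47 ± 0.17), Sema7a, a membrane semaphorin (-1.27 ± 0.16), and Papss2, a sulfate-activating enzyme (-1.26 ± 0.21).

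Of 19 mature single-positive genes 7 had a positive interaction, 16 positive and 1 negative adjusted over the list alone (adjusted p = 1.94e-19, and adjusted p = 0.162 with an estimated correlation), and of 20 TCR-induced genes Cd5 had a negative one, 9 adjusted over the list alone (adjusted p = 1.32e-07, and adjusted p = 0.255 with an estimated correlation). In all 10 lists were called, 4 up and 6 down, with 0 at an estimated correlation and 3 by fry. S1pr1 lost its call without WT 1, WT 2, WT 3, E2AKO 1, E2AKO 2, HEBKO 2 or DKO 3, Ms4a4b without WT 2, WT 3 or E2AKO 1, Papss2 without WT 3, E2AKO 1, HEBKO 2 or DKO 3, Cd226 without E2AKO 1 and Cd5 without E2AKO 2. The count of 83 was 27 without E2AKO 1, 50 without WT 3 and 54 without WT 2. On simulated data with 200 changed genes this term recovered 68.1% of 2-fold and 16.1% of 1.5-fold departures, so smaller departures could be missed.

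**Figure D3:**
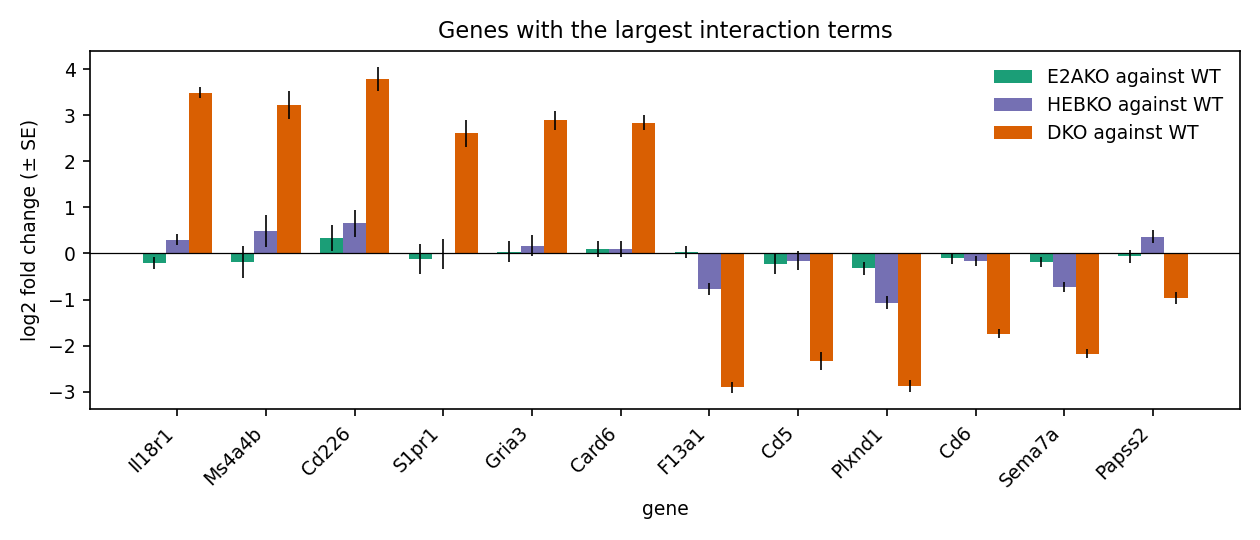
Log2 fold change against WT (y axis, bars, with SE) of the 12 named genes with the largest interaction terms (x axis) in E2AKO, HEBKO and DKO. Cd226 was 3.79 higher in DKO, and its interaction term was 2.80. The bars of Il18r1 and Gria3 in E2AKO and HEBKO rest on arrays below the 40th percentile and measure no fold.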

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

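The tests of mature T cells and of incomplete loss of HEB were chosen after the results were seen, and the 10 splits were set beforehand. Both patterns weighed here rest on 10 arrays, and genotype is the biological difference that the design names for each.

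The genotypes differed in their effect by a test of the difference itself, the interaction term, in 83 genes. Those named were Il18r1 at 3.40, Ms4a4b at 2.92, Cd226 at 2.80, S1pr1 at 2.74, Gria3 at 2.68 and Card6 at 2.64, and F13a1 at -2.16, Cd5 at -1.95, Plxnd1 at -1.49, Cd6 at -1.47, Sema7a at -1.27 and Papss2 at -1.26. Of these, Il18r1, Gria3, Card6 and S1pr1 lay below the 40th percentile of the array in some or all single knockout arrays, so their terms are not exact. A candidate explanation is that HEB was only partly lost in the HEBKO arrays, where the Tcf12 probe set, which does not measure intact messenger RNA, covered 69.9% and 40.6% of its DKO fall. The 67 positive genes covered a median of 2.70% of their DKO change in HEBKO (quartiles -3.82% to 8.91%) and the 16 negative genes 38.4% (15.4% to 50.1%). The term by which they were chosen contains the HEBKO change, so these shares decide nothing, and partial loss of HEB and a dependence on both factors cannot be told apart for either set.

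The falls and rises in DKO against WT were also weighed against mature T cells among the sorted cells, a population that a gate on CD4 and CD8 would be meant to remove. Mature T cells lack Rag1, Rag2 and Dntt, so their admixture alone would leave the same share of each. This holds only if intensity follows messenger RNA alike in each probe set, which was not checked. Dntt kept 50.2% of WT (40.6 to 62.1), Rag2 25.6% (18.3 to 35.9) and Rag1 32.1% (25.1 to 41.1), the last overlapping Dntt. Under that condition the gap between Dntt and Rag2 argues against admixture as the whole cause of the falls. On the same condition, admixture alone would need 49.8% other cells for Dntt, 67.9% for Rag1 and 74.4% for Rag2. The labels give over 98% DP cells for each DKO array. If the labels hold, these values argue against admixture as the main cause of these falls. For the rises, mature T cells hold much Cd5, and Cd5 kept 19.7% (14.7 to 26.4). Mature cells that lack E2A and HEB may express less Cd5 themselves, so Cd5 does not tell admixture from a change within DP cells. The labelled purity also limits admixture for the rises, but how large a rise it allows was not worked out. Fits of the 6 WT and DKO arrays alone gave 1718 genes for the real split and at most 4 for the others (1 of 10 splits as large as the real one), and 12 lists against at most 8 (1 of 10). With 10 splits no share under 0.05 can be reached.

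Probe sets outside the gene counts also differed in DKO against WT. Of 7288 with no symbol, 146 were called, 72 higher and 74 lower, and of 785 with several symbols, 73 were called, 49 higher and 24 lower. Against E2AKO, DKO had 66 called with no symbol and 22 with several, and HEBKO 7 (all lower) and 2 (both higher). In E2AKO against WT 1 with no symbol was called, at least 2-fold higher, although no named gene passed, and in HEBKO against WT 1, at least 2-fold lower. DKO against HEBKO had 1 with no symbol, and the interaction 0. These counts were not repeated without single arrays.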

How the results depend on the processing

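The sex term and the split of the WT arrays (given with the overlap in the report) were chosen after seeing the data, and the other alternatives were planned. Leaving out probe sets by the endings _x_at and _s_at was not run, since this array has no such endings. Without 1 array of E2AKO or HEBKO, the lone array is assumed to vary like the other groups. The array weights gave a warning that their tolerance was not reached. The labels state no pairing of mice by replicate number, so the block is given here only. Of 10 arrays, 5 lay closest to their own number in another group and 9 to their own sex. The genes from which sex was read were among those compared and pull arrays towards their own sex. The 9 is thus no measure of a wider effect of sex. In each knockout group replicate 1 was female and replicate 2 male, so these counts do not settle whether numbers pair the mice. Where not stated, the cause was not tested.

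For HEBKO against WT the 119 genes became 73 (32 up, 41 down) with arrays shifted to 1 median, 515 with array weights (306 up, 209 down), 36 with only the groups compared, 21 at 2-fold and 2 to 492 without 1 array (357 up, 135 down without WT replicate 2). For DKO against WT the 1786 became 3655 with array weights, 2321 with the block, 1413 with the sex term, 276 at 2-fold and 991 to 1910 without 1 array. For E2AKO the 0 became 1 with the block. For HEBKO against E2AKO the 5 became 3 (1 up, 2 down) with shifted arrays, 22 with trend and robust, 3 with only the groups compared, 86 with the block, 17 with the sex term and 0 to 55 without 1 array. For DKO against E2AKO the 1191 became 241 at 2-fold and 588 to 1290 without 1 array, for DKO against HEBKO the 477 became 129 and 193 to 499, and the 83 interaction genes became 43 with the block and 27 to 121 without 1 array. A 2-fold minimum lowers a count by construction.

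Tcf12 in HEBKO passed at -0.59 with renewed quantile normalisation, -0.52 with trend and robust and -0.53 with array weights, and lay between -0.36 and -0.69 without 1 array. Lists called with an estimated correlation were 0 in each of the 7 contrasts. With fry there were 1 in HEBKO, 0 in HEBKO against E2AKO and 3 in the interaction. With the block 3 were called in E2AKO. Without 1 array the lists called were 0 to 3 in E2AKO, 5 to 8 in HEBKO, 9 to 12 in DKO, 4 to 9 in HEBKO against E2AKO, 8 to 11 in DKO against E2AKO, 9 to 12 in DKO against HEBKO and 8 to 12 in the interaction. Medians turned sign without 1 array, with the lowest and highest being -0.37 and 0.18 for S-phase genes in E2AKO, -0.44 and 0.18 for mitosis genes in E2AKO (0.18 without E2AKO replicate 2), -0.057 and 0.54 for mature single-positive genes in HEBKO (-0.057 without HEBKO replicate 1), -0.24 and 0.21 for TCR-induced genes in HEBKO (0.21 without HEBKO replicate 2), -0.23 and 0.23 for TCR-induced genes in HEBKO against E2AKO (0.23 without HEBKO replicate 2), and -0.27 and 0.32 for S-phase genes in DKO against E2AKO (0.32 without E2AKO replicate 1). Mitosis genes in HEBKO against E2AKO ran from 0.17 to 0.84 and S-phase genes from 0.30 to 0.89. Of 84 named genes called in DKO, 69 kept their call in all settings run for named genes and 15 lost it in some. Those settings did not include the fit of only the groups compared. In HEBKO 2 of 29 kept it and 27 lost it in some. The overlap of E2AKO and HEBKO was 0 in all 5 alternatives run. Signal over background limits the reach, since 6799 dim genes were tested only in the fits with no filter.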

Other observations

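The gene families of the first 2 paragraphs and the genes next to Tcf12 were chosen after their values were seen, and the test of neighbouring genes was set before its result. Since the families were picked for their values, their adjusted p values, taken over the families chosen, are no independent evidence. Members of 4 families of immune genes rose in DKO, some of which (such as Gimap3, Slfn1 and Ms4a4b) also stand in the mature single-positive list fixed beforehand. Of 8 Gimap genes, GTPases of lymphocyte survival, 6 rose (adjusted p = 0.0746 by camera with an estimated correlation), of 7 genes of the Ifi200 family, which includes DNA sensors, 6 rose (median 1.26, adjusted p = 0.0668 with an estimated correlation), of 8 Slfn genes 4 rose (median 0.76, adjusted p = 0.0439 with an estimated correlation) and of 6 Ms4a genes 3 rose (adjusted p = 0.0713 with an estimated correlation). Of 6 Gbp genes 3 fell in HEBKO (median -0.64, adjusted p = 0.144 with an estimated correlation), and in DKO 3 fell and 1 rose (adjusted p = 0.123 with an estimated correlation). Of 5 T cell receptor alpha V segments with their own probe set 3 fell in DKO, Trav7n-5 at -2.13, Trav7d-4 at -1.52 and Trav13-5 at -0.44. Below the 40th percentile of the array lay Ifi214 in all 3 WT arrays, Ifi206 and Ifi213 in 2 of 3 and Trav7n-5 in 1 DKO array, so their changes are lower bounds on size.

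Of the families of energy and protein production, chosen in the same way, few members passed the test in HEBKO, and no family passed with an estimated correlation in HEBKO or DKO. Of 91 respiratory chain genes 82 had a positive change in HEBKO (median 0.34, 2 past the test, adjusted p = 0.144 with an estimated correlation) and 78 in DKO (median 0.29, 24 past the test, adjusted p = 0.123 with an estimated correlation). Of 66 cytosolic ribosome genes 59 had a positive change in HEBKO (median 0.35, 0 past the test in limma, adjusted p = 0.146 with an estimated correlation) and 60 in DKO (median 0.47, 36 past the test, adjusted p = 0.0746 with an estimated correlation). Of 38 proteasome genes 37 had a positive change in HEBKO (median 0.38, 0 past the test, adjusted p = 0.172 with an estimated correlation) and 31 in DKO (median 0.28, 7 past the test, adjusted p = 0.341 with an estimated correlation). Of 77 mitochondrial ribosome genes 68 had a positive change in HEBKO (median 0.25, 1 past the test, adjusted p = 0.172 with an estimated correlation) and 65 in DKO (median 0.23, 14 past the test, adjusted p = 0.226 with an estimated correlation).

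Myzap, the nearest tested gene on one side of Tcf12, was at -1.83 in HEBKO and -1.88 in DKO, with -0.05 ± 0.17 (SE) between them and 0.11 in E2AKO. It lay below the 40th percentile of the array in 1 of 2 HEBKO and 2 of 3 DKO arrays, so the small gap between them does not mean equal falls. Of the 10 tested genes nearest to Tcf12 in gene order, 5 per side, 4 fell in DKO (Myzap, Zfp280d at -0.59, Mns1 at -1.41 and Tex9 at -0.57), against 0 of 10 around Tcf3 by limma. Untested genes between them were passed over.

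In the order of tested genes, those at least 2-fold higher in DKO lay next to each other more often than chance, though untested genes may lie between. They formed 13 neighbour pairs against a mean of 1.54 in 10000 permutations (permutation p = 1e-04, the smallest they can give). Of these pairs 8 shared a symbol stem, such as Il18r1 with Il18rap and Ms4a4b with Ms4a6c, and related genes may share probe sequence. Pairs with different stems, such as Galc with Gpr65 and Card6 with Prkaa1, numbered 5, just above the 95th percentile of 4 (mean 1.47, permutation p = 0.0165). Card6 is also paired with Oxct1, and another pair joins Tent5c with Gm12474, a predicted gene. Symbol stems do not measure shared sequence, so these pairs do not decide on it. Genes at least 2-fold lower formed 13 pairs (mean 1.33), 10 of them with different stems, such as Gpr162 with Cd4, Iftap with Rag2 and Id3 with E2f2 (mean 1.27, permutation p = 1e-04). Those 10 count Myzap with Tcf12, a deleted gene, and Dgke with Dgkeos, its opposite-strand transcript, as unrelated pairs.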
